A study of Mus musculus with 8 samples.

How the data were processed

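RNA-seq and ribosome profiling were done on resting B cells and T cells from mouse spleen, with 2 libraries for each cell type and assay. Per the labels' protocols, the cells were sorted magnetically and kept in culture for 2 hours. Cells for ribosome profiling were treated with cycloheximide, at 100 µg/ml for 15 minutes, before lysis. RNA-seq was made with a TruSeq RNA v2 kit, which selects polyadenylated RNA, and read from both ends of each fragment. Footprints were taken from nuclease-treated monosomes and read from 1 end. The submitters' processing notes name FastQC, Bowtie2, TopHat and HTSeq and the mm10 build. Versions, settings, the counted feature, the use of strand, the annotation release and the treatment of ribosomal RNA are not given in the sources used here.

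The deposited values of the authors are counts per gene, per the labels and the values, which are whole numbers that sum to a different total in each library. They cover 53801 Ensembl gene IDs, of which 53620 have a symbol in the names table used and 38371 a gene class in the RefSeq table of GRCm38.p6. Of the count columns 0 were left unused. No row is named for unassigned reads. Library totals ran from 136433 to 627833 in footprints and from 8945905 to 10050986 in RNA-seq. Libraries of the same group differed by more than sampling noise. Chi-square over its degrees of freedom was 8.13 in B cell footprints, 5.35 in T cell footprints, 23.1 in B cell RNA-seq and 32.5 in T cell RNA-seq. The sources do not say that the libraries of a group come from separate animals, so the p-values measure the spread between these libraries. Sex-linked counts point to mice of different sex within each RNA-seq group. In B cells Xist and 4 Y-linked genes had 2362 and 8 counts in library 1 and 2 and 1616 in library 3. In T cells they had 1437 and 6 in library 1 and 3 and 1575 in library 4. B cell footprint libraries 1 and 3 had 72 and 53 Y-linked counts and T cell footprint libraries 1 and 2 had 3 and 35. Sex was therefore uneven over the groups. Floors of 3 counts cover counting error only.

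Counts were tested in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood test, TMM scaling and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. Genes entered with filterByExpr at a minimum count of 10 and a total of 15. B cells were compared with T cells in the 4 libraries of each assay, with 2 residual degrees of freedom. Translational efficiency was the contrast of assay and cell type in a model of all 8 libraries, with 4 residual degrees of freedom, and the footprints of each cell type were set against its mRNA in the same model. Log2 differences are B over T cells, or footprints over mRNA. The n is 2 libraries per group throughout, and a value after ± is a standard error for a log2 difference and a standard deviation for CPM. Group means in CPM use totals scaled by TMM. A gene without counts in a group is given as a bound, against 3 counts over that group.

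Gene lists, 33 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where 5 or more members were measured, and again with a correlation estimated from the data. List counts are given over all genes tested and adjusted over the list alone. The lists, the designs, the rule for named genes and all alternatives not named below as later were fixed before the data were examined. The genes named were, per comparison, the 6 with the largest difference in each direction that passed the threshold. Their libraries did not overlap, and their mean CPM was at least 10, or at least 5 in each assay where both were used. Variable, diversity and joining segments, predicted genes and genes without a symbol were left out. For each list up to 2 members with the smallest p in the main direction and 1 in the other were added. Among genes fixed to be given whatever their result were Ms4a1, Cd3e, Cd4, Actb, Gapdh, Fth1, Eef1a1 and Atf4. Agreement of the assays was measured over genes tested in both by Pearson and Spearman correlation and a total least squares slope.

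The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, limma voom, TMM within each assay, no filter beyond 1 count, a mean CPM of at least 10, removal of abundant gene classes, protein-coding genes alone, a test against a 1.5-fold change, all 8 libraries in a single fit, RNA-seq thinned to the smallest footprint library, a replicate block, and leaving out each library in turn. Chosen later, after seeing the data, were a term for the RNA-seq libraries numbered 1, a restriction to genes passing the footprint filter, and RLE scaling for the slope.

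The tests were tested on simulated data drawn at the depth and spread of these libraries, with 200 genes changed by known folds. In RNA-seq, over 13499 genes, 6.52% of genes changed 2-fold, 68.1% of those changed 4-fold and 89.8% of those changed 8-fold were recovered. In footprints, over 4301 genes, the shares were 8.70%, 60.9% and 93.5%. For translational efficiency, over 12833 genes, they were 0%, 4% and 31.2%, and over the 4475 simulated genes passing the footprint filter 0%, 0% and 76.9%. Within B cells, over 12595 genes, they were 0%, 42.6% and 49.0%, and within T cells, over 12660 genes, 0%, 36% and 77.1%. Of unchanged genes 0.158% were called in RNA-seq, 0.0728% in footprints, 0.00791% for translational efficiency, 0.0806% within B cells and 0.0722% within T cells. In RNA-seq these were 21 genes, beside 3, 32, 44 and 46 recovered at 2, 4, 8 and 16-fold. Within B cells they were 10, beside 0, 20, 24 and 37, and within T cells 9, beside 0, 18, 37 and 34. For translational efficiency over genes passing the footprint filter they were 3, beside 0, 0, 20 and 23. In these cases the unchanged share of called genes exceeded the test's threshold, unlike in footprints or for translational efficiency over 12833 genes. With no list shifted, 1 of 29 lists was called in RNA-seq, 0 of 26 in footprints and 0 of 29 for translational efficiency. The simulated genes were drawn independently of each other, so these counts do not show how camera errs where genes vary together.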

Results

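B cells and T cells from the spleens of B6 mice were studied in the resting state, after magnetic sorting and 2 hours in culture. Their mRNA was measured by RNA-seq. Their translation was measured by ribosome profiling, which sequences the mRNA fragments, or footprints, that ribosomes protect from nuclease. The 8 libraries fell into 4 groups of 2, with a group for each cell type and assay. They carried the submitters' numbers 1 and 3 for B cells in both assays, 1 and 4 for T cell RNA-seq and 1 and 2 for T cell footprints. The RNA-seq libraries held 9466190 and 8989740 counts in B cells and 10050986 and 8945905 in T cells. The footprint libraries held 236810 and 232568 counts in B cells and 627833 and 136433 in T cells. The smallest RNA-seq library was 14.2 times as deep as the largest footprint library. Levels are in CPM, counts scaled to a common library total, and 1 count stood for 1.59 to 7.33 CPM in the footprint libraries against 0.0995 to 0.112 in RNA-seq. Small nuclear and nucleolar RNA genes took 2.76% and 10.6% of the counts of B cell footprint libraries 1 and 3 and 9.30% and 18.6% of those of T cell footprint libraries 1 and 2. In RNA-seq their largest share was 0.010%.

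The sorted populations carried the markers of their own lineage in both assays. Ms4a1, which encodes the B cell surface protein CD20 (ENSMUSG00000024673, chromosome 19, 11249679 to 11266149 in GRCm38.p6), had 1021 ± 33.3 CPM in B cell RNA-seq against 13.5 ± 11.0 in T cells (mean ± SD, n = 2 libraries). Cd3e, a chain of the T cell receptor complex (ENSMUSG00000032093, chromosome 9, 44998735 to 45009663), had 404 ± 42.4 CPM in T cell RNA-seq against 19.8 ± 22.6 in B cells. Genes of the other lineage were present at low levels that differed between libraries. The median T cell identity gene stood at 0.670% of its T cell level in B cell RNA-seq library 1 and at 10.5% in library 3, and at 1.59% and 5.98% in B cell footprint libraries 1 and 3. B cell identity genes other than immunoglobulins stood at 1.33% and 1.75% of their B cell level in T cell RNA-seq libraries 1 and 4 and at 1.84% and 5.12% in T cell footprint libraries 1 and 2. Immunoglobulin genes took 1.54% of the counts of T cell RNA-seq library 1 and 0.182% of those of library 4.

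**Figure D1:**
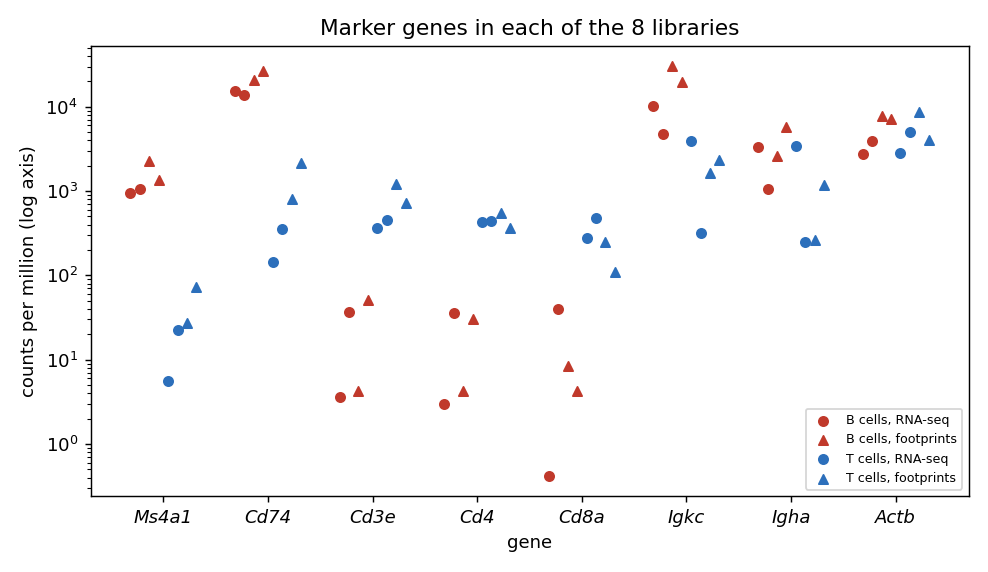
CPM (log axis) of 8 genes in each of the 8 libraries, with B cells in red, T cells in blue, circles for RNA-seq and triangles for footprints. Ms4a1 and Cd74 are higher in every B cell library than in any T cell library and Cd3e, Cd4 and Cd8a the reverse, while Igkc and Igha differ between the T cell RNA-seq libraries, with Igkc at 3955 CPM in library 1 and 318 in library 4.

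The first comparison asked which mRNAs differ between resting B and T cells. In RNA-seq, 1310 genes were higher and 1262 lower in B cells among 13929 tested, 1058 and 1038 of them by at least 2-fold. The largest differences towards B cells included that of Cacna1i, a calcium channel subunit (143 ± 3.08 against 0.886 ± 0.391 CPM; log2 difference 7.32 ± 0.27 SE, adjusted p = 0.00162). Ebf1, a transcription factor that specifies the B lineage, was close behind (181 ± 29.8 against 1.14 ± 0.324 CPM; 7.30 ± 0.27, adjusted p = 0.00162). Fcer2a, the low-affinity IgE receptor, followed at 7.28 ± 1.01, the kinase gene Srpk3 at 7.28 ± 0.29 and Fcmr, the IgM receptor, at 7.10 ± 0.66. The microRNA gene Mir5107 (7.53 ± 0.30) lies inside Cd74, so that its counts cannot be assigned with certainty, and Cacna1i and Fcer2a overlap other annotated genes, as do Tgfbr3, Slc6a19 and Trat1 below. The largest differences towards T cells were those of Tnfsf8, the CD30 ligand (0.987 ± 1.08 CPM in B cells against 37.8 ± 4.99 in T cells; -5.23 ± 0.71, adjusted p = 0.0140). Next came Lcn4 (-5.03 ± 1.03), Tgfbr3 (-5.03 ± 1.04), the amino acid transporter gene Slc6a19 (-4.85 ± 1.04), the T cell receptor adaptor gene Trat1 (-4.81 ± 0.86) and Ly6c1 (-4.73 ± 0.89). Actb (-0.19 ± 0.32, adjusted p = 0.751) and Gapdh (-0.26 ± 0.18, adjusted p = 0.381) did not pass the test.

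Of the 28 B cell identity genes, 27 were higher in B cells, the same number when adjusted over the list alone. The median log2 difference was 6.04 (camera adjusted p = 4.76e-67; adjusted p = 0.456 with an estimated correlation). Bcl11a, a transcription factor of early B cell development, stood at 6.25 ± 0.16, the Fc receptor-like gene Fcrla at 6.03 ± 0.18 and Ms4a1 at 6.24 ± 0.74. All 12 genes of MHC class II presentation were higher, 12 also when adjusted over the list alone, with a median of 5.91 (camera adjusted p = 4.61e-24; adjusted p = 0.570 with an estimated correlation). H2-Oa and H2-Ob, which encode a modulator of peptide loading, stood at 3.81 ± 0.15 and 4.20 ± 0.18. In the list of Toll-like receptors and innate sensing, 9 of 18 members were higher and 1 was lower in B cells, or 12 and 2 adjusted over the list alone. The list's median was 2.00 (camera adjusted p = 1.93e-11; adjusted p = 0.570 with an estimated correlation). Cd180, a Toll-like receptor homologue of B cells, and Ly86, its partner, stood at 5.64 ± 0.23 and 5.20 ± 0.24, whereas Myd88, the adaptor of most Toll-like receptors, was lower (-0.52 ± 0.11, adjusted p = 0.0372).

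The 30 T cell identity genes had lower estimates in B cells throughout, with a median of -4.19. Of these 8 passed the test over all genes and 27 when adjusted over the list alone (camera adjusted p = 4.94e-11; adjusted p = 0.993 with an estimated correlation). Cd28, the co-stimulatory receptor, stood at -4.54 ± 0.73 (adjusted p = 0.0206) and the kinase gene Lck at -3.23 ± 0.56, while Cd3e (-4.35 ± 1.06, adjusted p = 0.0534) and Cd4 (-4.49 ± 1.12, adjusted p = 0.0571) did not pass. The level of the T cell identity genes in B cells was the one that differed between libraries 1 and 3. Their median was -3.23 without B cell library 1 and -7.10 without B cell library 3. With 1 B cell library left, the spread between B cell libraries no longer enters the test, so only medians are given for these 30 genes. Of the 14 markers of activated, regulatory and effector T cells, 11 were lower in B cells, 14 adjusted over the list alone (median -3.21, camera adjusted p = 5.02e-11; adjusted p = 0.803 with an estimated correlation). The list's median was -2.62 without B cell library 1 and -4.19 without B cell library 3. Ikzf2, a transcription factor of regulatory T cells, stood at -4.61 ± 0.39 and Tnfrsf18 at -1.46 ± 0.15. Natural killer cell markers were lower in 6 of 14, 10 adjusted over the list alone (median -2.33, camera adjusted p = 7.03e-05; adjusted p = 0.993 with an estimated correlation). Their median was -1.83 without B cell library 1 and -3.55 without B cell library 3. The count was 10 without B cell library 3 and 3 without T cell library 4. With a term for the libraries numbered 1, chosen after seeing the data, 22 of the 30 T cell identity genes were lower (median -4.92). So were 14 of the 14 activated, regulatory and effector T cell markers and 11 of the 14 natural killer markers. That fit kept only 1 residual degree of freedom. Gzmb, granzyme B, stood at -2.32 ± 0.37 and Klrc1 at -3.18 ± 0.60.

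In the list of cytokine and homing receptors 7 of 20 members were higher in B cells and 4 were lower, or 7 and 6 adjusted over the list alone, without a shift of the list (camera adjusted p = 0.885). Tnfrsf13b and Tnfrsf13c, receptors for B cell survival factors, stood at 2.90 ± 0.14 and 5.61 ± 0.35 and Il6st, the shared signalling chain of the interleukin 6 family, at -3.06 ± 0.23. Of 18 quiescence regulators, 4 were higher, among them Tsc22d3 (1.73 ± 0.16), and 2 were lower, among them Satb1 (-1.83 ± 0.20); the counts were the same adjusted over the list alone (camera adjusted p = 0.885). In the glycolysis list 5 of 19 genes were lower and 1 was higher, 5 and 2 adjusted over the list alone (camera adjusted p = 0.463). Ldhb, a lactate dehydrogenase subunit, stood at -3.98 ± 0.55, Hk1, a hexokinase, at -1.03 ± 0.13 and Aldoc at 1.78 ± 0.27. No ribosomal protein gene passed among 82 (median -0.28, camera adjusted p = 0.0668), and none did among 34 proteasome and 76 nuclear-encoded oxidative phosphorylation genes, with 0 in each adjusted over the list alone. Of the plasma cell markers Irf4 (3.87 ± 0.51) and Mzb1 (3.95 ± 0.93) were higher among 9, 3 adjusted over the list alone, beside the immunoglobulin counts of T cell RNA-seq library 1 (median 1.99, camera adjusted p = 0.0570). The count of 2572 genes rested in part on the B cell libraries, being 1455 without library 1 and 1626 without library 3. Against a 1.5-fold change 1509 genes passed, and 497 passed when RNA-seq was thinned to the depth of the smallest footprint library.

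The second comparison asked which genes differ in ribosome footprints. B cells had more footprints than T cells for 400 genes and fewer for 229 among 4771 tested, all by at least 2-fold. Several genes had footprints in both libraries of one cell type and no count in the other, so that their fold is a lower bound taken against 3 counts over the group. Bcl11a was at least 50.7-fold higher in B cells (199 ± 103 CPM, adjusted p = 0.000453). Next were the Ras activator gene Rasgrp3 (at least 30.3-fold), Zfp608 (at least 25.3-fold), Lyl1 (at least 21.0-fold), B3gnt8 (at least 18.5-fold) and the basement membrane gene Nid1 (at least 17.3-fold). In the other direction Cd6, a T cell surface receptor, was at least 50-fold lower in B cells (366 ± 11.0 CPM in T cells, adjusted p = 0.000321). It was followed by Ramp3 (at least 44.0-fold), Cd247, the zeta chain of the T cell receptor complex (at least 37.6-fold), Izumo1r (at least 14.7-fold), Cd40lg, which encodes the CD40 ligand (at least 14.6-fold), and Pkp4 (at least 14.0-fold). Bcl11a, Zfp608, Lyl1, Ramp3 and Cd247 overlap another annotated gene, and the counting strand is not given in the sources used here. Actb (0.41 ± 0.64, adjusted p = 0.794) and Gapdh (-0.21 ± 0.40, adjusted p = 0.836) did not pass.

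The lineage lists separated the cells in footprints as well. All 28 B cell identity genes had more footprints in B cells, 28 also adjusted over the list alone (median 5.26, camera adjusted p = 1.01e-49; adjusted p = 0.400 with an estimated correlation). The median was 4.23 without T cell library 1. Fcer2a stood at 5.70 ± 0.55 and the adaptor gene Blnk at 5.20 ± 0.53. Of the 30 T cell identity genes 29 had fewer, 29 also adjusted over the list alone (median -4.54, or -4.51 with the 3 genes that had no count in B cells at their bound; camera adjusted p = 1.17e-44; adjusted p = 0.400 with an estimated correlation). The median was -3.86 without B cell library 1 and -5.86 without B cell library 3. Lat, the adaptor of T cell receptor signalling, had 2.63 ± 3.72 CPM in B cells against 548 ± 43.6 in T cells (-7.56 ± 0.72, adjusted p = 0.000321). Trac, the constant region of the receptor's alpha chain, stood at -6.31 ± 0.63. Cd3e (-4.92 ± 0.73, adjusted p = 0.000923) and Cd4 (-4.56 ± 0.63, adjusted p = 0.000607) both passed. All 12 MHC class II genes had more footprints in B cells, 12 also adjusted over the list alone. Its median was 4.0 (camera adjusted p = 1.89e-18; adjusted p = 0.400 with an estimated correlation). The list's median was 3.49 without T cell library 1 and 4.77 without T cell library 2. Its members included Ciita, the transcriptional activator of the class (5.61 ± 0.57). In the same libraries the MHC class II genes stood at 3.94% and 9.18% of their B cell level in T cell footprint libraries 1 and 2, against 1.0% and 2.74% in T cell RNA-seq libraries 1 and 4.

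Among the 8 measured genes of the Toll-like receptor list, 7 had more footprints in B cells, or 7 more and 1 fewer adjusted over the list alone (median 3.69, camera adjusted p = 2.07e-09; adjusted p = 0.400 with an estimated correlation). Cd180 stood at 4.85 ± 0.50 and Ly86 at 4.53 ± 0.53. Of 10 activated, regulatory and effector T cell markers 9 had fewer, 9 also adjusted over the list alone (median -4.01, or -3.53 with 1 gene at its bound; camera adjusted p = 2.73e-11; adjusted p = 0.400 with an estimated correlation). The fitted median was -7.11 without B cell library 3. B cell library 1, then alone, had counts for only 6 of the 14 members of the full list, so that this value is not a measured size. The co-stimulator Icos stood at -7.18 ± 0.82 and Tnfrsf4 at -5.44 ± 0.74. The natural killer list lay lower in B cells as a set (median -1.57, camera adjusted p = 0.00776; adjusted p = 0.851 with an estimated correlation), although 0 of its 7 measured members passed, 0 also adjusted over the list alone. This rested on the B cell libraries, with 7 of 8 lower and a median of -4.14 without library 3, and 0 of 8 and -0.79 without library 1. Of 18 immediate-early and dissociation response genes 9 had more footprints in B cells and 2 fewer, or 11 and 3 adjusted over the list alone. The median stood at 1.57 (camera adjusted p = 0.0174; adjusted p = 0.400 with an estimated correlation). The transcription factor genes Fosb (3.36 ± 0.49, adjusted p = 0.000860) and Egr3 (3.77 ± 0.61) were higher and Fosl2 (-2.35 ± 0.69) was lower. These genes varied between libraries of one cell type: Fos, chosen after its values were seen, had 991 CPM in B cell footprint library 1 and 76.7 in library 3.

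Smaller groups followed single members. Among cytokine and homing receptors 3 of 19 had more and 3 fewer footprints in B cells, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.298). Tnfrsf13c stood at 7.13 ± 0.79, Cxcr5, the follicle homing receptor, at 3.41 ± 0.46 and Il7r at -4.31 ± 0.61. The protein disulfide isomerase genes Pdia4 (2.68 ± 0.48, adjusted p = 0.00280) and Pdia6 (1.71 ± 0.39, adjusted p = 0.0112) were higher. They belong to the secretory pathway list, in which 3 of 25 passed and 6 adjusted over the list alone (camera adjusted p = 0.298). Among the quiescence regulators Klf4 (3.55 ± 0.68) was higher and Satb1 (-2.15 ± 0.53) lower, and Zfp36l2, an mRNA decay factor, was lower (-2.10 ± 0.48). Vars, the valyl-tRNA synthetase, was higher in both assays, at 1.59 ± 0.16 in RNA-seq and 1.77 ± 0.41 in footprints, and Ldhb was lower in footprints by at least 7.91-fold. The count of 629 genes was 415 without T cell footprint library 1, the deepest of the 4.

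Where 5 or more members were measured, the other lists fixed in advance did not shift as sets in either assay (camera adjusted p = 0.463 and above in RNA-seq and 0.172 and above in footprints, apart from the lists given above), but single members passed over all genes. The stromal and endothelial list and the platelet list, with 3 and 2 members measured in RNA-seq, were not tested as sets there. MHC class I presentation had 2 of 13 lower in B cells in RNA-seq, Nlrc5 (-1.26 ± 0.14) and Erap1 (-0.75 ± 0.12), 2 also adjusted over the list alone, and 1 of 13 lower in footprints, 0 adjusted over the list alone. Among RNA-binding and translation regulators 3 were higher and 3 lower of 32 in RNA-seq, the same adjusted over the list alone, with Zfp36l1 at 1.19 ± 0.15 and Pdcd4, an inhibitor of translation, at -0.98 ± 0.14. Iron and polyamine feedback mRNAs had 1 higher and 2 lower of 16, the same adjusted over the list alone, with Fth1 at 1.02 ± 0.21. Selenoproteins had 2 lower of 15, 1 adjusted over the list alone, mitochondrial ribosomal proteins 1 higher and 2 lower of 75, 0 adjusted over the list alone, and aminoacyl-tRNA synthetases 1 higher of 20, 1 adjusted over the list alone. Counts were also small for uORF-regulated mRNAs (1 lower of 12), stromal and endothelial markers (1 higher of 3) and dendritic cell markers (1 higher and 1 lower of 8), the same adjusted over the list alone. Monocyte and macrophage markers had 1 lower of 17, 0 adjusted over the list alone. Translation initiation factors (31 measured in RNA-seq), replication-dependent histones (24), other 5' TOP mRNAs (20), neutrophil markers (6), erythroid markers (6) and platelet markers (2) had 0 in RNA-seq, 0 also adjusted over the list alone. In RNA-seq 4 of 27 secretory pathway genes were higher and 1 lower, and 3 of 21 immediate-early genes were higher and 2 lower, with the same counts adjusted over the list alone. The immediate-early list (median 0.05) turned on single libraries, with 6 higher and 1 lower (median 1.12) without T cell library 1, 2 higher and 6 lower (median -0.87) without T cell library 4 and 2 higher and 0 lower (median -0.50) without B cell library 1. It had 3 higher and 0 lower (median 0.32) without B cell library 3, and 5 higher and 2 lower (median 0.31) with the term for the libraries numbered 1. Of 28 cell cycle genes 1 was higher and 1 lower, 0 adjusted over the list alone. Pdia4 stood at 1.54 ± 0.16 and Egr3 at 1.93 ± 0.14. In footprints 3 of 48 histone genes were higher in B cells, among them Hist1h2bc (1.67 ± 0.44), and 0 adjusted over the list alone. The 13 mitochondrially encoded genes had no count in any library.

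The third comparison asked how far the difference in footprints follows that in mRNA. Over 4660 genes tested in both assays the log2 differences had a Pearson correlation of 0.84 and a Spearman correlation of 0.66 across genes, which are not independent replicates, and a total least squares slope of 1.23. Of the genes called in both assays 276 were higher in B cells and 140 in T cells, against 45.6 and 20.3 expected for independent lists, and 0 were called in opposite directions. Of 553 genes called only in RNA-seq 90.6% had the same sign in footprints, as had 97.0% of the 198 called only in footprints in RNA-seq and 62.7% of those called in neither. The slope depended on single libraries, at 0.94 without B cell RNA-seq library 3 and 1.60 without B cell footprint library 3. With RNA-seq thinned to the smallest footprint library it was 1.01 over 2617 genes. Total least squares takes the error as equal in both assays, whereas the footprint libraries held far fewer counts. The slope of 1.23 therefore does not show that differences in footprints exceed those in mRNA.

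**Figure D2:**
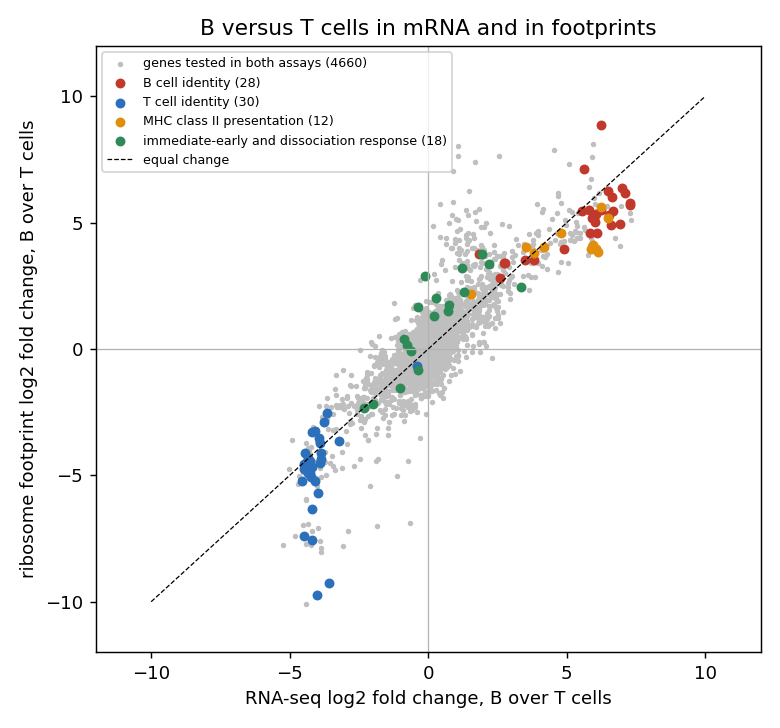
Log2 fold change of B over T cells in RNA-seq (horizontal) and in ribosome footprints (vertical) for the 4660 genes tested in both assays, in grey, with 4 gene lists in colour and a dashed line of equal change. The lineage lists lie at opposite corners, with median footprint differences of 5.26 for B cell identity and -4.54 for T cell identity; the fitted value of a gene with no footprint count in one cell type is not a measured size.

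The fourth comparison asked whether footprints per mRNA, the translational efficiency, differ between B and T cells. No gene passed the edgeR test among 13227, with a smallest adjusted p of 0.818 and 748 genes at an unadjusted p under 0.05 where chance gives 661. DESeq2 called 10 genes and limma voom 0. Among those DESeq2 called, chosen after their values were seen, Stat5a, which relays cytokine signals, had a lower translational efficiency in B cells. Its DESeq2 log2 difference was -3.78 (adjusted p = 0.00509). That size rests on 2 and 3 footprint counts in B cell libraries 1 and 3, against 128 and 47 in T cell libraries 1 and 2. Translational efficiency was also lower for the cytokine receptor genes Il4ra (-1.41, adjusted p = 0.000171) and Il21r (-1.87, adjusted p = 0.0477). So it was for Gabpb1 (-2.57, adjusted p = 4.05e-05), P2ry10 (-2.05), Crbn (-1.74), Birc3 (-1.52) and Gimap6 (-1.24). It was higher for Lrrc8c (1.68, adjusted p = 0.0406) and Lasp1 (1.40, adjusted p = 0.0485). In edgeR, Fth1, the ferritin heavy chain, stood at -1.28 ± 0.43, with an adjusted p of 0.875. On simulated counts of the same depth and spread, the test recovered 0% of genes changed 2-fold, 4% of those changed 4-fold and 50% of those changed 16-fold among 12833 genes. Most differences of 4-fold or less were therefore not detectable at this depth and n.

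As sets, 7 of 30 lists differed in translational efficiency by camera, none of them with an estimated correlation. Higher in B cells were the lists of immediate-early genes (median 1.07, adjusted p = 0.00438), natural killer markers (1.76, adjusted p = 0.00693) and dendritic cell markers (2.38, adjusted p = 0.0478), each with an adjusted p of 0.893 with an estimated correlation. The natural killer list took its direction from B cell footprint library 3, without which it reversed (adjusted p = 0.957). Other 5' TOP mRNAs were higher too (0.36, adjusted p = 0.0179; adjusted p = 0.922 with an estimated correlation). Lower in B cells were B cell identity genes (-0.65, adjusted p = 0.00483), MHC class II genes (-0.89, adjusted p = 0.00693) and cytokine and homing receptors (-0.24, adjusted p = 0.0179), each with an adjusted p of 0.893 with an estimated correlation. Of the members of these lists 0 passed over all genes, and 3 cytokine and homing receptors passed adjusted over the list alone. The immediate-early list summed to 13003 CPM in T cell RNA-seq library 1 and 5146 in library 4, against 11407 and 8957 in B cell RNA-seq libraries 1 and 3. These mRNA levels enter the median of 1.07 given for that list. Leaving T cell RNA-seq library 1 out also lowered the number of genes tested from 13227 to 9867. Without T cell RNA-seq library 1, the one rich in immunoglobulin counts, 1 list passed and it was none of these 7.

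The fifth comparison set footprints against mRNA within each cell type, to show which mRNAs carry more or fewer ribosomes than others. It also holds the difference between the library types, since the RNA-seq kit named in the labels selects polyadenylated RNA and the footprint protocol does not. Cycloheximide treatment is given for the footprint cells only, so that its effect cannot be told apart from that of the assay. In B cells 861 genes had more and 1623 fewer footprints than their mRNA level would give, and in T cells 1178 and 2464, among 13227 tested. With the test and scaling of DESeq2 together the splits were 1428 and 1504 in B cells and 1692 and 2202 in T cells. With RLE scaling alone, in edgeR, they were 1013 and 1459, and 1371 and 2147. Over the 4771 genes passing the footprint filter the B cell split was 584 and 619, with a median log2 ratio of 0.01. With RNA-seq thinned to the smallest footprint library it was 491 and 513 over 4297 genes, with a median of 0.09. The excess of lower genes in B cells thus depended on which genes were tested. The median gene stood at a log2 ratio of -0.44 in B cells and -0.54 in T cells, or -0.24 and -0.35 with DESeq2, and the values given here are to be read against these medians. The ratios of the 2 cell types had a correlation of 0.77 across genes. In all, 639 genes were higher in both and 1292 were lower in both, against 76.7 and 302 expected for independent lists, and 1 was called in opposite directions.

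Ribosomal protein mRNAs had few footprints in both cell types. In B cells 69 of 82 were lower, 70 adjusted over the list alone. Over the list the median was -2.70 (camera adjusted p = 1.89e-35; adjusted p = 0.586 with an estimated correlation). In T cells 71 were lower and 1 higher, with the same counts adjusted over the list alone. The list's median was -2.83 (camera adjusted p = 1.05e-42; adjusted p = 0.403 with an estimated correlation). Rpl12 had 23.1 ± 13.4 CPM of footprints against 2858 ± 339 CPM of mRNA in B cells (-6.93 ± 0.47, adjusted p = 0.000144) and 46.9 ± 0.174 against 4567 ± 457 in T cells (-6.60 ± 0.44, adjusted p = 0.000145). Rpsa (-5.57 ± 0.42) and Rps15a (-4.90 ± 0.52) were lower in B cells, and Rpl17 (-5.52 ± 0.41), Rpsa (-5.42 ± 0.41) and Rps18 (-4.73 ± 0.45) in T cells. The member higher in T cells was Rpl24 (2.70 ± 0.68), at 2.39 ± 0.851 CPM of mRNA. Other mRNAs with a 5' terminal oligopyrimidine (TOP) motif include many that encode translation factors. Of the 20 in this list 13 were lower in B cells, 15 adjusted over the list alone. Its median was -1.54 (camera adjusted p = 2.45e-08; adjusted p = 0.586 with an estimated correlation). In T cells 17 of 20 were lower, 18 adjusted over the list alone. The median stood at -1.92 (camera adjusted p = 7.46e-11; adjusted p = 0.596 with an estimated correlation). Tpt1 stood at -5.01 ± 0.45 in B cells and -5.02 ± 0.44 in T cells, and Eef1a1, the elongation factor, at -2.58 ± 0.38 and -2.97 ± 0.39. The medians of both lists stayed negative, and below that of all genes, in both cell types with RLE, upper-quartile and DESeq2 scaling and with TMM within each assay. Ribosomal protein genes have many near-identical pseudogene copies and several of those named contain small nucleolar RNA genes, so that their single values are uncertain.

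The replication-dependent histones lay at the opposite end, with 53 of 57 higher in each cell type, 53 also adjusted over the list alone. Their median was 7.69 in B cells (7.66 with genes without counts at their bound; camera adjusted p = 1.29e-57; adjusted p = 0.406 with an estimated correlation). In T cells it was 7.05 (camera adjusted p = 5.34e-94; adjusted p = 0.204 with an estimated correlation). Most histone mRNAs of this list lack a poly-A tail. Hist1h1c had 3278 ± 501 CPM of footprints against 92.4 ± 18.9 CPM of mRNA in B cells (5.15 ± 0.42, adjusted p = 0.000297) and stood at 5.26 ± 0.43 in T cells. Hist1h2bc stood at 6.14 ± 0.41 in B cells. Small nuclear and nucleolar RNA genes, which encode no protein, were higher in footprints in 87 of 107 in B cells and 95 of 107 in T cells. Among them Snora31, which lies inside Tpt1, stood at 8.35 ± 1.04 in T cells.

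**Figure D3:**
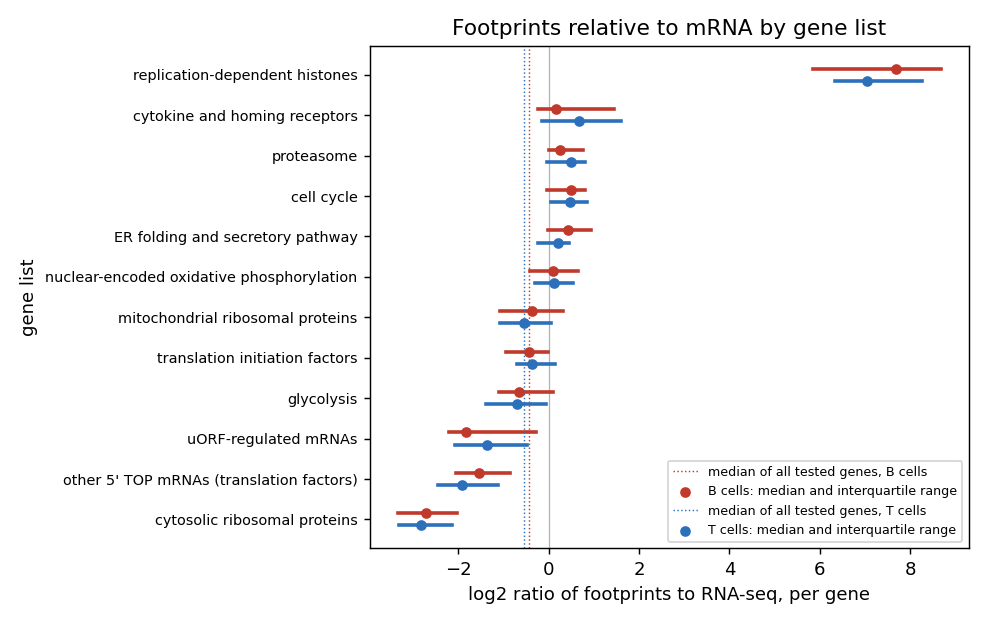
Log2 ratio of footprints to RNA-seq for 12 gene lists, with the median (point) and interquartile range (bar) over each list's measured genes in B cells (red) and T cells (blue) and the median of all tested genes as dotted lines. Ribosomal protein genes lie lowest, at medians of -2.70 and -2.83, and replication-dependent histones highest, at 7.69 and 7.05.

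Single homing receptor mRNAs had many footprints, while their list was divided in B cells. Cxcr4, the receptor for the chemokine CXCL12, stood at 4.03 ± 0.37 in B cells and 4.19 ± 0.38 in T cells, and Ccr7, which directs lymphocytes into lymph nodes, at 2.36 ± 0.33 and 3.13 ± 0.34. Their list had 6 higher and 2 lower of 20 in B cells, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.586 with an estimated correlation). In T cells 7 were higher, 7 also adjusted over the list alone (camera adjusted p = 7.38e-05; adjusted p = 0.403 with an estimated correlation). Its B cell median was 0.16, and -0.02 when only genes passing the footprint filter were tested. Lnpep, a membrane aminopeptidase, stood at 5.25 ± 0.33 in B cells and 4.61 ± 0.32 in T cells. In B cells the zinc finger gene Zfp871 stood at 4.34 ± 0.59 and Tlr9 at 3.91 ± 0.39. In T cells the transcription factor genes Crem and Nr4a3 stood at 5.66 ± 0.46 and 4.48 ± 0.78 and Ramp3 at 5.14 ± 0.74. Among the genes with few footprints outside the ribosomal list were Tctn1 (-6.02 ± 0.45), which overlaps Hvcn1, and Cep85 (-5.38 ± 0.68) in B cells and Fam193b (-4.99 ± 0.56) in T cells. Fam193b, Crem and Ramp3 also overlap other annotated genes.

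Proteasome genes were higher in 5 of 34 in B cells and 9 of 34 in T cells, 4 and 9 adjusted over the list alone, with 1 lower in T cells so adjusted. Camera gave an adjusted p of 0.00475 and 0.00102 (adjusted p = 0.586 and 0.627 with an estimated correlation). Psmc6 stood at 1.51 ± 0.28 and 1.51 ± 0.27. Of the secretory pathway genes 5 of 27 were higher in B cells and 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00246; adjusted p = 0.586 with an estimated correlation). The chaperone gene Hsp90b1 stood at 2.69 ± 0.31 and Pdia4 at 2.08 ± 0.38. Cell cycle genes were higher in 3 of 28 in B cells and 7 of 28 in T cells, 0 and 7 adjusted over the list alone (camera adjusted p = 0.00891 and 0.0224; adjusted p = 0.586 and 0.841 with an estimated correlation). In T cells 5 of 14 markers of activated, regulatory and effector T cells were higher, 6 adjusted over the list alone (camera adjusted p = 0.0116; adjusted p = 0.841 with an estimated correlation). They included Cd44 (1.80 ± 0.33) and Tnfrsf18 (1.48 ± 0.22). Genes of the other lineage also passed in T cells, with 5 of 12 MHC class II genes higher, 5 adjusted over the list alone. Of 28 B cell identity genes 2 were higher and 1 lower, 0 adjusted over the list alone (camera adjusted p = 0.0224 for each list; adjusted p = 0.841 with an estimated correlation). B cell genes made up a larger share in T cell footprint library 2 than in T cell RNA-seq, as given above.

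Further lists passed as sets in B cells alone, which was not tested as a difference between the cells except by the interaction above. Of all 13 lists that passed within B cells, 3 stayed past the threshold with a mean CPM of at least 10. With genes passing the footprint filter 3 did. Within T cells 5 and 3 of 9 lists stayed. Most set results within B cells thus depended on which genes were tested. Quiescence regulators had 4 higher and 1 lower of 18, the same adjusted over the list alone, with Foxo1 at 1.58 ± 0.33 (camera adjusted p = 0.0289; adjusted p = 0.631 with an estimated correlation). Oxidative phosphorylation genes had 10 higher and 6 lower of 76, 11 and 6 adjusted over the list alone (camera adjusted p = 0.0471; adjusted p = 0.739 with an estimated correlation). Their median was 0.09, and -0.10 with only genes passing the footprint filter. Ndufa5 stood at 2.31 ± 0.26 and Ndufb11 at -1.37 ± 0.27. Aminoacyl-tRNA synthetases (0 of 20; camera adjusted p = 0.0429; adjusted p = 0.645 with an estimated correlation) and monocyte and macrophage markers (0 of 17; camera adjusted p = 0.0471; adjusted p = 0.739 with an estimated correlation) passed without any member. Natural killer markers, Gzma and Prf1, were higher in 2 of 14, 2 also adjusted over the list alone (camera adjusted p = 0.00475; adjusted p = 0.645 with an estimated correlation), and neutrophil markers in 5 of 10, 5 also adjusted over the list alone (camera adjusted p = 0.0429; adjusted p = 0.645 with an estimated correlation). The natural killer list summed to 114 CPM in B cell footprint library 1 and 679 in library 3. Within cells, mitochondrial ribosomal proteins (8 and 14 of 75 lower in B and T cells, 2 and 1 higher, with 13 lower in T cells and no other change adjusted over the list alone) and translation initiation factors (6 lower of 31 in each, 1 and 3 higher, with 7 lower and 4 higher in T cells adjusted over the list alone) did not pass as sets (camera adjusted p = 0.494 and 0.365, and 0.174 and 0.831). Nor did iron and polyamine feedback mRNAs (6 and 4 of 16 lower, 6 in each adjusted over the list alone; camera adjusted p = 0.116 and 0.609) or glycolysis genes (4 and 7 of 19 lower, 4 and 8 adjusted over the list alone; camera adjusted p = 0.283 and 0.246). The neutrophil gene S100a9 had 4.22 CPM in B cell footprint library 1 and 279 in library 3.

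Among genes whose translation responds to iron or stress, Ftl1, the ferritin light chain, stood at -3.62 ± 0.39 in B cells and -3.44 ± 0.39 in T cells. Atf4, whose upstream reading frames hold back its translation in unstressed cells, was lower in B cells (-2.87 ± 0.61, adjusted p = 0.0138) and did not pass in T cells (-1.72 ± 0.58, adjusted p = 0.0556). The difference between the cell types did not pass either (-1.15 ± 0.82, adjusted p = 0.904). Ppp1r15a, another mRNA of this kind, stood at -3.33 ± 0.73 in T cells, and 3 of 12 of the list were lower in each cell type, 4 and 5 adjusted over the list alone (camera adjusted p = 0.116 and 0.214). Fth1 was lower in B cells (-1.30 ± 0.31, adjusted p = 0.0222), with -0.02 ± 0.30 in T cells, and Gpx4, a selenoprotein, stood at -2.68 ± 0.38 in B cells and -1.15 ± 0.30 in T cells. The counts in B cells were 1524 and 1281 without RNA-seq library 1 or 3 and 1520 without footprint library 3. Those in T cells were 947 without footprint library 1 and 2288 without RNA-seq library 4, and with genes passing the footprint filter 1203 genes were called in B cells and 1559 in T cells.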

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

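The tests of carry-over between the sorted cells, pooled and by library, were chosen only after the result was seen, and the reading of the test of low counts was given its margin after its value was seen. For 7 gene lists the ratio of footprints to mRNA differed between B and T cells, by the test of the difference itself. As medians of B minus T cells on the log2 scale these were -0.89 for MHC class II genes, -0.65 for B cell identity genes and -0.24 for cytokine and homing receptors. The others were 0.36 for other 5' TOP mRNAs, 1.07 for immediate-early genes, 1.76 for natural killer markers and 2.38 for dendritic cell markers. The last 3 lists hold 2, 1 and 1 genes without counts in a group. With an estimated correlation 0 of the 7 passed. Without T cell RNA-seq library 1, 1 list passed in all, and it was none of these.

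The lower values of MHC class II and B cell identity genes in B cells were weighed against 2 technical explanations. B cell RNA among the T cells stays open. The median B cell identity gene without immunoglobulins stood, as a mean over libraries, at 1.54% of its B cell level in T cell RNA-seq. In T cell footprints it stood at 3.48%. Taken as carry-over, this predicts -1.17 for MHC class II genes, where -0.89 was observed. The value cannot decide, because it is itself the footprint-to-mRNA difference of B cell identity genes in the same libraries. A difference in translation shared by both lists would give the same value. The prediction rests on T cell footprint library 2, being -1.73 from it alone (-1.74 observed without library 1) and -0.26 from library 1 alone (-0.40 observed without library 2). Low counts stay open too, because the 19 of 40 members with 20 or more T cell footprint counts had a median of -0.33 with a bootstrap standard error of 0.368, and the bound set in advance was -0.3, so that low counts and a true difference cannot be told apart in these members. The other members had a median of -0.76. T cell footprint counts also enter the difference itself, so that a split by them is not independent of it. A difference in translation between the cell types, which the design names, stays among the open explanations and was not tested apart from carry-over.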

How the results depend on the processing

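Settings chosen only after the result was seen were the term for libraries numbered 1, the restriction to genes passing the footprint filter and RLE scaling of the slope. In RNA-seq, 2572 genes passed, 1509 against a 1.5-fold change and 497 with thinned RNA-seq. Other settings but leaving out libraries gave 1718 to 3755. In footprints the same settings gave 479 to 918 genes, against 629. For translational efficiency DESeq2 called 10 genes and the other settings without a replicate block 0. Within B and T cells, 2484 and 3642 genes passed, against 1004 and 1296 with thinned RNA-seq and 1203 and 1559 with genes passing the footprint filter. Fewer counts or genes tested account for the thinned and filtered values by construction, and for the others the cause was not tested.

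Leaving out 1 library gave 1455 to 1973 genes in RNA-seq, 415 to 898 in footprints, 0 to 0 for translational efficiency, 1281 to 2571 within B cells and 947 to 4154 within T cells. The lone library of a group was taken to vary like the other groups. The slope ran from 0.94 to 1.60 and the correlation across genes from 0.696 to 0.863. The correlation was 0.790 with a mean CPM of at least 10 and 0.606 with no filter, which add genes with few footprints.

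With an estimated correlation 0 lists passed in each of the 5 comparisons, against 6 in RNA-seq, 7 in footprints, 7 for translational efficiency, 13 within B cells and 9 within T cells. With no filter 11 passed for translational efficiency and 17 within T cells. A mean CPM of at least 10 gave 4 for translational efficiency, 3 within B cells and 5 within T cells, and genes passing the footprint filter gave 4 in each of these. Leaving out 1 library gave 7 to 9 lists in RNA-seq, 7 to 10 in footprints, 1 to 12 for translational efficiency, 7 to 14 within B cells and 5 to 11 within T cells. The cause was not tested.

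The direction of some list tests reversed without 1 library. For translational efficiency the adjusted p ran from 7.66e-13 to 0.949 for T cell identity (reversed without B cell RNA-seq library 3), from 1.44e-07 to 0.957 for natural killer markers (0.957 without B cell footprint library 3) and from 0.00254 to 0.758 for monocyte and macrophage markers (0.00254 without T cell RNA-seq library 4). It ran from 0.00316 to 0.657 for ribosomal proteins (reversed without B cell footprint library 3, 0.0107) and from 0.0288 to 0.974 for aminoacyl-tRNA synthetases (0.0288 without B cell footprint library 1). Within B cells it ran from 1.86e-06 to 0.811 for T cell identity (reversed without B cell RNA-seq library 1, 0.00242). Oxidative phosphorylation reversed with genes passing the footprint filter (0.751). The cause was not tested.

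Of the values of named genes under these settings, 0 changed sign where the main fit or the alternative passed the threshold. Where neither passed, 2 changed sign in RNA-seq, 5 in footprints, 7 within B cells, 32 within T cells and 19 for translational efficiency. In RNA-seq 973 of 1108 kept both their sign and their side of the threshold. In footprints 663 of 719 did so, within B cells 1501 of 1652 and within T cells 1566 of 1751. For translational efficiency 188 of 207 did so.

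The numbers do not establish pairs across assays. Footprint and RNA differences between numbers correlated across genes at 0.110 in B cells and -0.0733 in T cells, the T cell groups share only number 1 across assays, and B cell RNA-seq library 1 had 8 counts of 4 Y-linked genes against 72 in B cell footprint library 1. In T cells libraries 1 were alike in this, with 6 and 3 such counts. Within RNA-seq the differences of B and T cells correlated at 0.464, so that number 1 goes with a shared difference there, although the other numbers, 3 and 4, are not shared. With the replicate block 87 genes were called for translational efficiency, 68 higher and 19 lower in B cells, with 1 residual degree of freedom, and 0 with the block as a random effect. It called 2161 genes within B cells, 2184 with the B cell libraries alone, and 1684 within T cells. Depth limits the footprint comparisons, where 1 count is 1.59 to 7.33 CPM.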

Other observations

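The tests of immunoglobulin counts and of libraries numbered 1 were chosen only after the result was seen, as was the matching with repeats. RNA-seq libraries numbered 1 differed alike from those numbered 3 and 4 in both cell types. In an added edgeR fit 4 genes were higher and 7 lower in them among 13929. Hspa1b, a heat shock gene, stood at 8.07 ± 0.26 (adjusted p = 0.0144). The related gene Hspa1a, chosen after its values were seen, had 418 and 403 CPM in B and T cell libraries 1 against 3.10 in B cell library 3 and 0.881 in T cell library 4 (adjusted p = 0.0769). The complement gene C1qb and the adhesion gene Vcam1 lay the other way, at -8.04 ± 0.23 (adjusted p = 0.0144) and -6.69 ± 0.31 (adjusted p = 0.0364), and 4 of 17 monocyte and macrophage markers were lower. Xist was higher (9.49 ± 0.25) and the Y-linked genes Kdm5d (-6.61 ± 0.25) and Eif2s3y were lower in libraries 1. Eif2s3y had 0 counts in both libraries 1, against 907 in B cell library 3 and 815 in T cell library 4, so that no size is given. With a term for the set, 3755 genes differed between B and T cells in RNA-seq, among them 2537 of the 2572 found without it.

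Immunoglobulin mRNAs were abundant in T cell RNA-seq library 1, where Igkc stood at 37.3%, Igha at 99.2% and Jchain at 73.5% of their level in B cell RNA-seq library 1. Ordinary B cells among the T cells are argued against, since B cell identity genes other than immunoglobulins stood at 1.33%. Reads of that B cell library are argued against as well, since its abundant mRNA Cd74 stood at 0.905%. Plasma cells or their RNA are a candidate source: the 9 plasma cell markers, 1 of which had no count in library 4, were all higher in library 1 than in library 4, by a median ratio of 6.63, while B cell identity genes had a median ratio of 0.568. The same 9 markers were all higher in B cell RNA-seq library 1 than in library 3 too, with Jchain at 1394 and 250 CPM. Their difference thus goes with the libraries numbered 1 in both cell types and is not particular to the T cells. Intact plasma cells and free RNA were not separated by any test, all 9 markers also had counts in B cell RNA-seq, and the magnetic sort named in the labels would in principle remove such cells.

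Ribosomal protein mRNAs had few footprints, and this was weighed against 2 technical explanations. High abundance is argued against, since other genes matched on mRNA level, with repeats, had medians of -0.53 in B and -0.92 in T cells, against -2.70 and -2.83. The median mRNA of these matches was 1778 and 2174 CPM, against 1776 and 2169 for ribosomal protein genes. With each match counted once, 123 genes in B cells and 93 in T cells had medians of -0.41 and -0.78. Their median mRNA was lower, at 977 and 1141.5 CPM, so that this set is not fully matched. Reads lost to pseudogenes stay open: ribosomal protein genes without a named pseudogene stood at -2.06 in B and -2.55 in T cells and those with at -2.84 and -2.91, with a Spearman correlation across genes of -0.374 (permutation p = 0.00051) in B cells and -0.287 (permutation p = 0.00893) in T cells. Against pseudogenes, 21 other genes with 3 or more of them had medians of only -0.67 and -0.73, so that the bound set in advance was met, but only 15.8% of 10442 pseudogenes carry the name of a parent gene, a coverage limit applied after the values were seen, so that the 2 possibilities cannot be told apart for these genes. No biological explanation was tested, since the design has no activated cells.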
